A study of Mus musculus with 2 samples.

How the data were processed

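Adrenal glands of female C57BL/6J mice that carry SF1-Cre and floxed Znrf3 alleles were dissociated into single cells, and 1 library was made per age, from 2 adrenals at 6 weeks and from 3 adrenals at 9 weeks. Per the labels' protocols, red blood cells were lysed, and viable single cells that took up the DNA dye Vybrant DyeCycle Ruby and excluded DAPI were sorted before capture with the Chromium 3' v3.1 chemistry, which reads the 3' end of each transcript and marks each molecule with a unique molecular identifier (UMI). The deposited values are counts of UMIs per gene and barcode, as whole numbers that the authors had not normalized. Per the submitters' processing notes, Cell Ranger 6.0.1 and the genome build mm10 were used, and Seurat is named without a version. The annotation release behind the counts is not given in the sources used here. No annotation of cell types was used, so clusters and class names were rebuilt, and a difference from the study may come from these rebuilt names.

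The 6-week matrix held 8880 barcodes and 97001752 UMIs, with a median of 11540 UMIs and 3331 genes per barcode. The 9-week matrix held 10812 barcodes and 99728879 UMIs, with medians of 7174.5 UMIs and 2334.5 genes. Counts of rows with the same symbol were summed, which took 32285 rows to 32245 symbols. Barcodes with under 500 genes (161 at 6 weeks, 221 at 9 weeks) and then those with over 25% mitochondrial UMIs (111 and 64) were removed. Doublets were called per library with Scrublet in scanpy 1.11.5, at an expected rate of 0.8% per 1000 cells, and removed. It called 489 cells at 6 weeks (5.68%, with 6.89% expected) and 595 at 9 weeks (5.65%, with 8.42% expected). This left 8119 cells with 86288611 UMIs at 6 weeks and 9932 cells with 88549249 UMIs at 9 weeks.

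Both libraries were clustered together without integration. Counts were log-normalized per cell, 2000 variable genes other than mitochondrial, ribosomal protein and haemoglobin genes were standardized, and 30 principal components and 20 nearest neighbours entered Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A cluster took the name of the class, followed by "-like", with the highest mean level over the fixed markers of 20 classes. It needed at least 3 markers that were found in 10% of its cells and stood 2 times above the median cluster. Clusters in which another class came to 0.5 of the best score, or whose 10 leading genes held more markers of another class, stayed unnamed. T cells and NK or innate lymphoid cells were joined as T/NK. In all 61 clusters resulted. The names follow clusters of both libraries, so a cluster that is mostly from 1 library may reflect that library and not a cell type.

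Classes with at least 50 cells in each library were compared, which gave 8 classes. UMIs were summed per class and library and scaled to the total UMIs of that class (CPM), each level with its exact Poisson 95% interval. The log2 ratio of 9 over 6 weeks used a pseudocount of 5 CPM, which pulls the ratios of weakly expressed genes towards 0. Shares of cells carry exact Clopper-Pearson 95% intervals. Ratios carry a range made from the bounds of both ages, low over high and high over low, which is wider than a 95% interval. With 1 library per age no test across libraries was possible, so no p-value was computed. For 29 gene lists, members needed 10 CPM in 1 library and 10 UMIs over both, and a list needed 5 such members. The median log2 ratio over members was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries only. Members were counted as higher or lower from a 1.5-fold ratio of the levels with the pseudocount. For cycling cells, each cell was thinned to 2000 UMIs and counted where it held at least 2 UMIs over 11 mitotic genes, and shallower cells were left out. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and figures matplotlib 3.10.9. Gene coordinates come from GENCODE M21 on mm10.

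The sample groups, the marker genes, the lists, the comparisons, the rule for named genes and most of the alternatives were fixed before the data were examined. That rule took, in each class, genes at 50 CPM or more with 30 UMIs and UMIs in 10% of cells in the library where they were higher, a log2 ratio of at least 1 in size, and a level of at least 20% of that in any other class. It left out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes and genes named only by a clone or model number. The 10 largest ratios each way were taken in adrenocortical-like and macrophage-like cells and the 5 largest in other classes, and list members could be named with their values. Several choices were made after the data had been seen. These were the scoring and thresholds of the class names, the joining of T and NK cells, the second clustering without cycle genes of clusters led by at least 3 cell cycle genes, and the rule that leaves a cluster unnamed where it held 6 markers of another lineage with a score of at least 0.15. The same holds for the choice of the lists described per class. In all 155 pairs of class and list could be measured and 86 of them lay at or past the 2.5th or 97.5th percentile; 50 pairs that concern known properties of the class, dissociation stress, or a list set beside the same list of another class are described.

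The alternatives covered the filters on genes, mitochondrial share and doublets, the clustering, class names per cell, the pseudocount, the scaling, the mean over cells, the filter on low genes, and subtraction of free RNA. The last took a multiple of the library's whole profile, between 0.843% and 5.17% of the UMIs of a class, that brought the most abundant marker of another lineage to 0. Added after the data were seen were the largest cluster of a class alone, clusters weighted alike at both ages (clusters of at least 20 cells in each library, each with the same weight in both), cycle-led clusters left whole, and clusters of mixed lineage kept in a class. Clusters are themselves built from expression, so weighting them alike can also take away part of a difference within a cell type.

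The calculation was tested on 20 simulated data sets made from the macrophage-like sums, with 200 changed genes among a median of 7742 measured genes. The Poisson intervals covered the true level in 98.2% of cases, which bears on counting error only. Genes changed 2-fold had a median log2 ratio of 0.95 and genes changed 4-fold 1.89, and 27.7% and 100% of them passed a log2 ratio of 1. Of unchanged genes at 50 CPM or more with 30 UMIs, 0% did. A list of 25 genes changed 2-fold always lay at percentile 100, and of 20 unchanged lists 3 lay past the 2.5th or 97.5th percentile. Without replicates, differences between animals or preparations could not be estimated, so these rates do not cover them. Only the macrophage-like sums were simulated. The rates were not tested for classes with fewer UMIs, such as neutrophil-like and B cell-like cells.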

Results

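Single-cell RNA sequencing was carried out on adrenal glands of female mice in which Cre recombinase under the SF1 promoter, active in steroid-producing cells of the adrenal cortex, deletes Znrf3, a ubiquitin ligase that limits Wnt signalling. The labels give 6 weeks as the age of cortical overgrowth and 9 weeks as the age at which the gland shrinks, and the question is how the immune environment of the gland differs between these ages once senescence has set in. There was 1 library per age, from 2 adrenals at 6 weeks and 3 adrenals at 9 weeks, so there are no replicates, and every comparison is of these 2 libraries. All intervals cover counting error only. After filtering and doublet removal, 8119 cells with a median of 11347 UMIs remained at 6 weeks and 9932 cells with a median of 7028.5 UMIs at 9 weeks. Within classes the depth gap went the other way for most immune cells. Macrophage-like cells, for example, had medians of 5931 and 7131 UMIs, while adrenocortical-like cells had 15538 and 14788.5.

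Znrf3 RNA (ENSMUSG00000041961, mm10 chromosome 11, 5276324 to 5444847, minus strand) was found mainly in adrenocortical-like cells at both ages. It stood at 45.1 CPM (43.5 to 46.7) at 6 weeks and 53.9 CPM (51.4 to 56.5) at 9 weeks, a ratio of 1.20 (1.1 to 1.30). UMIs of Znrf3 were found in 47.5% and 51.0% of these cells, against 4.42% and 4.43% of macrophage-like cells at their lower depth. The 3' tag may lie outside the deleted part of the gene and both libraries have the same genotype, so this level checks neither the deletion nor the labels.

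Immune cells made up a larger part of the gland's cells at 9 weeks and adrenocortical-like cells a smaller part. All immune classes together held 27.2% of cells (26.3 to 28.2) at 6 weeks and 60.3% (59.3 to 61.2) at 9 weeks, a ratio of 2.21. Adrenocortical-like cells held 53.1% (52.0 to 54.2) and 21.3% (20.5 to 22.2). Dendritic-like and neutrophil-like cells had the largest ratios among the classes compared, at 3.30 (2.78 to 3.92) and 3.06 (2.48 to 3.80), and dendritic-like cells held 3.50% (3.11 to 3.92) and 11.5% (10.9 to 12.2). Endothelial-like cells differed least, with 18.9% (18.0 to 19.8) and 16.0% (15.3 to 16.8).

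**Figure D1:**
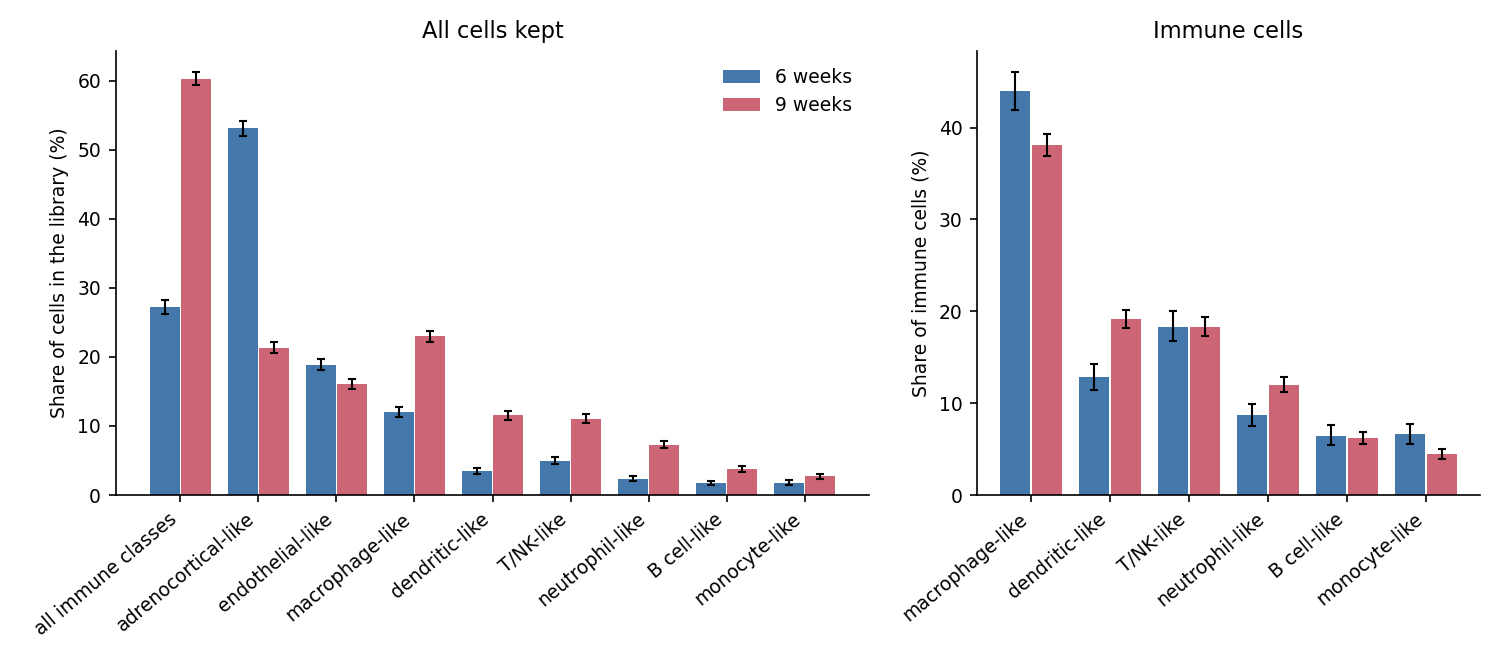
Share of cells per class at 6 and 9 weeks, in percent of all cells kept (left) and of immune cells (right); bars are the 2 libraries and error lines exact 95% Clopper-Pearson intervals. Immune classes together stand at 27.2% and 60.3% of cells, and dendritic-like cells at 12.8% and 19.1% of immune cells.

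Macrophage-like cells were the most numerous immune class at both ages, with 12.0% of cells (11.3 to 12.7) at 6 weeks and 22.97% (22.1 to 23.8) at 9 weeks. T/NK-like cells stood at 4.99% (4.52 to 5.48) and 11.0% (10.4 to 11.7), neutrophil-like cells at 2.36% (2.05 to 2.72) and 7.24% (6.74 to 7.77), B cell-like cells at 1.76% (1.49 to 2.07) and 3.74% (3.37 to 4.13), and monocyte-like cells at 1.80% (1.52 to 2.11) and 2.69% (2.38 to 3.03). Within the immune cells (2211 and 5987), the dendritic-like share was higher at 9 weeks, with 12.8% (11.5 to 14.3) and 19.1% (18.2 to 20.2), as was that of neutrophil-like cells, with 8.68% (7.54 to 9.94) and 12.0% (11.2 to 12.9). The immune share of macrophage-like cells was lower at 9 weeks, with 44.0% (41.9 to 46.1) and 38.1% (36.9 to 39.3), as was that of monocyte-like cells, with 6.60% (5.60 to 7.72) and 4.46% (3.95 to 5.01). T/NK-like cells held 18.3% of immune cells at both ages. Of the neutrophil-like cells, cluster 9 held 190 of 192 at 6 weeks and 436 of 719 at 9 weeks, or 2.34% and 4.39% of all cells. Cluster 13, led by genes of immature granulocytes such as Camp, Ngp and Ltf, held 2 and 283 cells, or 0.0246% and 2.85%. Cluster 9 alone thus differed less between the ages than the class. Plasmacytoid dendritic-like cells (0.370% and 0.483%), mast/basophil-like cells (0.234% and 0.473%) and plasma cell-like cells (0.246% and 0.111%) were few.

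These shares are of viable single cells sorted by a DNA dye after red blood cell lysis, and the libraries differ in depth. A minimum of 1000 genes per cell, which removes most neutrophil-like cells at 6 weeks, gave a neutrophil ratio of 14.4 in place of 3.06, above the dendritic ratio, which was at most 4.04. Cells of unnamed clusters were 0.714% at 6 weeks and 2.07% at 9 weeks. Thresholds set after the data were seen kept 0.431% and 0.463% of cells out of the classes as clusters of mixed lineage.

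Mitotic cells were more frequent at 9 weeks over all cells kept. At 2000 UMIs per cell, 2.09% (1.77 to 2.45) and 6.12% (5.63 to 6.63) were cycling, a ratio of 2.92 (2.29 to 3.74), with 1048 and 941 shallower cells left out, and without thinning the shares were 3.45% and 10.4%. The 8 classes compared held 133 and 396 of these cycling cells, or 1.92% (1.61 to 2.27) and 4.57% (4.14 to 5.03) of their cells, and the cells outside them held 15 of 130 and 154 of 317. Among the latter were 9 of 11 and 64 of 73 cells of unnamed clusters with markers of dendritic and other cells. Dendritic-like cells had the highest share at both ages, with 12.5% (8.86 to 17.0) and 15.1% (13.1 to 17.3), or 24.3% and 33.2% unthinned (4 and 15 cells left out). Macrophage-like cells had 4.44% (3.19 to 6.00) and 6.62% (5.61 to 7.74), or 6.996% and 10.9% unthinned (71 and 105 left out). T/NK-like cells had 8.29% (5.62 to 11.7) and 4.81% (3.58 to 6.31), or 8.64% and 8.11% unthinned (55 and 79 left out). Adrenocortical-like cells had 0.470% (0.287 to 0.725) and 1.01% (0.627 to 1.54), or 1.74% and 4.39% unthinned (54 and 42 left out). Within these 4 classes the thinned intervals of both ages overlapped, also with the unnamed clusters just given counted as dendritic-like, at 15.1% (11.2 to 19.8) and 19.5% (17.3 to 21.9). Unthinned, they overlapped in T/NK-like cells only. They lay apart in adrenocortical-like (1.37 to 2.18 and 3.56 to 5.35), macrophage-like (5.47 to 8.78 and 9.67 to 12.3) and dendritic-like cells (19.4 to 29.7 and 30.5 to 36.1). Median depth was higher at 9 weeks in the last 2 of these classes and lower in adrenocortical-like cells. The thinned overlap thus does not show equal shares. Endothelial-like cells, at 0.815% and 0.499%, show the level in a class with few dividing cells (674 and 392 left out, 0.522% and 1.13% unthinned). The thinned shares of T/NK-like, endothelial-like and monocyte-like cells (1.40% and 0.758%) were lower at 9 weeks, each with overlapping intervals. The share over all cells also depends on the mix of classes. Dendritic-like, T/NK-like and macrophage-like cells had the highest cycling shares of the 8 classes at both ages. They made up more of the cells at 9 weeks, and adrenocortical-like cells fewer (53.1% and 21.3%). How much of the ratio of 2.92 came from this mix was not calculated.

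In adrenocortical-like cells, genes of the zona glomerulosa, the outer aldosterone-producing zone, were higher at 9 weeks, as were Wnt target genes, while cholesterol synthesis genes were lower. The fasciculata and steroidogenesis lists had medians under 0, with members that went both ways. These differences went with which cortical clusters the cells came from. Clusters 2 and 3 held 1285 and 1197 of the 4308 cells at 6 weeks and 152 and 60 of the 2120 cells at 9 weeks, while clusters 4 and 6 held 571 and 393 cells at 6 weeks and 678 and 588 at 9 weeks. With clusters weighted alike at both ages, the glomerulosa and Wnt medians turned to the other side of 0 and those of the fasciculata and cholesterol lists came close to 0.

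Of 12 zona glomerulosa genes measured, 11 were higher at 9 weeks by 1.5-fold and 1 was lower, with a median log2 ratio of 1.13 (percentile 100 of random lists). Dab2, a glomerulosa marker, stood at 310.0 CPM (305.9 to 314.3) and 769.1 CPM (759.5 to 778.8), and Hsd3b6 at 98.0 and 271.3 CPM. The gene that was lower, Cyp2f2, leads cluster 3. Of 11 Wnt targets, 8 were higher and 0 lower (median 0.66, percentile 99.995), among them Ccnd1 (102 and 249.6 CPM), Lef1 (17.1 and 44.9 CPM) and Axin2 (30.6 and 51.2 CPM), a direct target of beta-catenin. Of 18 cholesterol biosynthesis genes, 13 were lower and 0 higher (median -0.80, percentile 0), with Fdps at 275.3 and 116.1 CPM and Hmgcs1, an early enzyme of the pathway, at 371.4 and 181.8 CPM. The fasciculata list had a median of -0.48 (percentile 0.08), with 4 of 10 genes lower and 3 higher. Cyp11b1, the last enzyme of corticosterone synthesis, stood at 2615 and 1676 CPM and Srd5a2 at 302.1 and 121 CPM, while Cyp11a1, which makes pregnenolone from cholesterol, stood at 1096 and 2411 CPM and Akr1b7 at 215.1 and 486.3 CPM. The steroidogenesis list had a median of -0.26 (percentile 0.44), with 5 of 16 genes lower, such as Cyp21a1 (7843 and 4644 CPM), and 3 higher. Cyp11b1 and Cyp21a1 are also among the leading genes of cluster 2, and Cyp11a1 of cluster 6. The mean over members was -0.15 for the fasciculata list (percentile 24.5) and -0.15 for steroidogenesis (percentile 14.8). The steroidogenesis list also had a median under 0 in macrophage-like (-0.42, 5 of 13 genes lower by 1.5-fold) and T/NK-like cells (-0.47, 4 of 10), which are not steroid-producing. Whether its members there were free RNA was not tested. Weighting the clusters alike gave -0.090 for glomerulosa, -0.062 for Wnt targets, -0.022 for cholesterol biosynthesis, -0.016 for fasciculata and -0.077 for steroidogenesis.

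Genes of the p53 pathway and cell cycle arrest went both ways in adrenocortical-like cells. The median of the 13 p53 and senescence genes was 0.039 (percentile 36.0), with 2 genes higher by 1.5-fold, Btg2 (16.3 and 42.7 CPM) and Phlda3 (10.85 and 20.3 CPM), and 0 lower. The cycle inhibitor Cdkn1a stood at 24.2 CPM (23.02 to 25.4) and 29.3 CPM (27.5 to 31.3), and Cdkn2a at 22.4 CPM (21.3 to 23.5) and 13.9 CPM (12.6 to 15.2). With a trimmed mean scaling, which puts a log2 factor of -0.17 on the 9-week levels of this class, the median was -0.11. Of 11 secreted senescence factors, 6 were higher and 0 lower (median 0.59, percentile 99.96), with Igfbp7, which leads cluster 6 beside other genes, at 1094 and 2289 CPM and Timp2 at 14.5 and 40.02 CPM. One further member, Ccl5, stood at 1.71 and 17.2 CPM, and at 4857 and 4915 CPM in T/NK-like cells. The median of that list was 0.042 without doublet removal, 0.071 with at least 1000 genes per cell and 0.10 with clusters weighted alike.

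Genes of interferon response and antigen presentation were higher in adrenocortical-like cells at 9 weeks, also with clusters weighted alike. Of 14 MHC class I genes, 7 were higher and 0 lower (median 0.53, percentile 100, and 0.58 with clusters weighted alike). B2m, the shared light chain of class I molecules, stood at 358.6 CPM (354.1 to 363.2) and 888.8 CPM (878.5 to 899.3), H2-K1 at 621.3 and 1268 CPM, and Psmb8, of the immunoproteasome, at 66.7 and 199.5 CPM. Of 25 interferon response genes, 8 were higher and 0 lower (median 0.37, percentile 99.98, and 0.27 with clusters weighted alike), among them Iigp1 (25.02 and 56.7 CPM), an interferon-induced GTPase, and Bst2 (194.5 and 313.0 CPM), a restriction factor of enveloped viruses. All but 1 of the 8 MHC class II genes were higher (median 1.76), but at low levels. Cd74, the invariant chain, stood at 33.2 and 183.3 CPM, against 72.3 and 682.7 CPM in neutrophil-like cells, which should lack most of it. Myeloid genes that cortical cells should lack were higher too, with Tyrobp at 3.69 and 20.6 CPM and C1qa at 5.05 and 25.7 CPM, and with free RNA subtracted the interferon, class I and class II medians were 0.37, 0.51 and 1.74. The subtraction thus left the class II median near 1.76 although these myeloid genes were higher too. It therefore cannot decide how much free RNA added to these lists.

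The largest ratios in this class, by the fixed rule, were those of Nr4a1 (13.2 and 128.0 CPM, log2 2.87), Nr4a2 (2.39), Htra1 (2.11), Tpm2 (2.09), Id1 (1.89), Rims2 (1.78), Caln1 (1.60), Cttnbp2 (1.60), Kitl (1.54) and Bok (1.54). Nr4a1 and Nr4a2 are nuclear receptors induced early by stimulation, and Nr4a2 is also in the glomerulosa list. Nr4a1 and Btg2 are members of the dissociation stress list as well, of which 5 of 14 genes were higher and 0 lower (median 0.30, percentile 99.7), with Egr1 at 1.29 and 14.5 CPM and Dusp1 at 8.45 and 31.3 CPM. With clusters weighted alike this median was -0.027. Kitl, the ligand of Kit, stood at 33.2 CPM (31.8 to 34.6) and 106.3 CPM (102.7 to 109.9). The lowest ratios, beside those of Cyp2f2 and C3, which lead cluster 3, were those of A2m (-2.36), Pttg1 (-2.14), Thrsp (-2.01), Cdh13 (-1.92), Cryba4 (-1.84), Fry (-1.68), Fmo1 (-1.68) and Top1mt (-1.64). A2m, a protease inhibitor, stood at 210.3 CPM (206.8 to 213.8) and 36.8 CPM (34.7 to 39.0). With clusters weighted alike, Nr4a1 (2.01), Nr4a2 (1.58), A2m (-1.21), Pttg1 (-2.68) and Cryba4 (-1.03) still had a log2 ratio of at least 1 in size, and the other genes were under it. In cluster 2 alone, Nr4a2 (-0.054) and Rims2 (-0.28) were lower at 9 weeks.

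**Figure D2:**
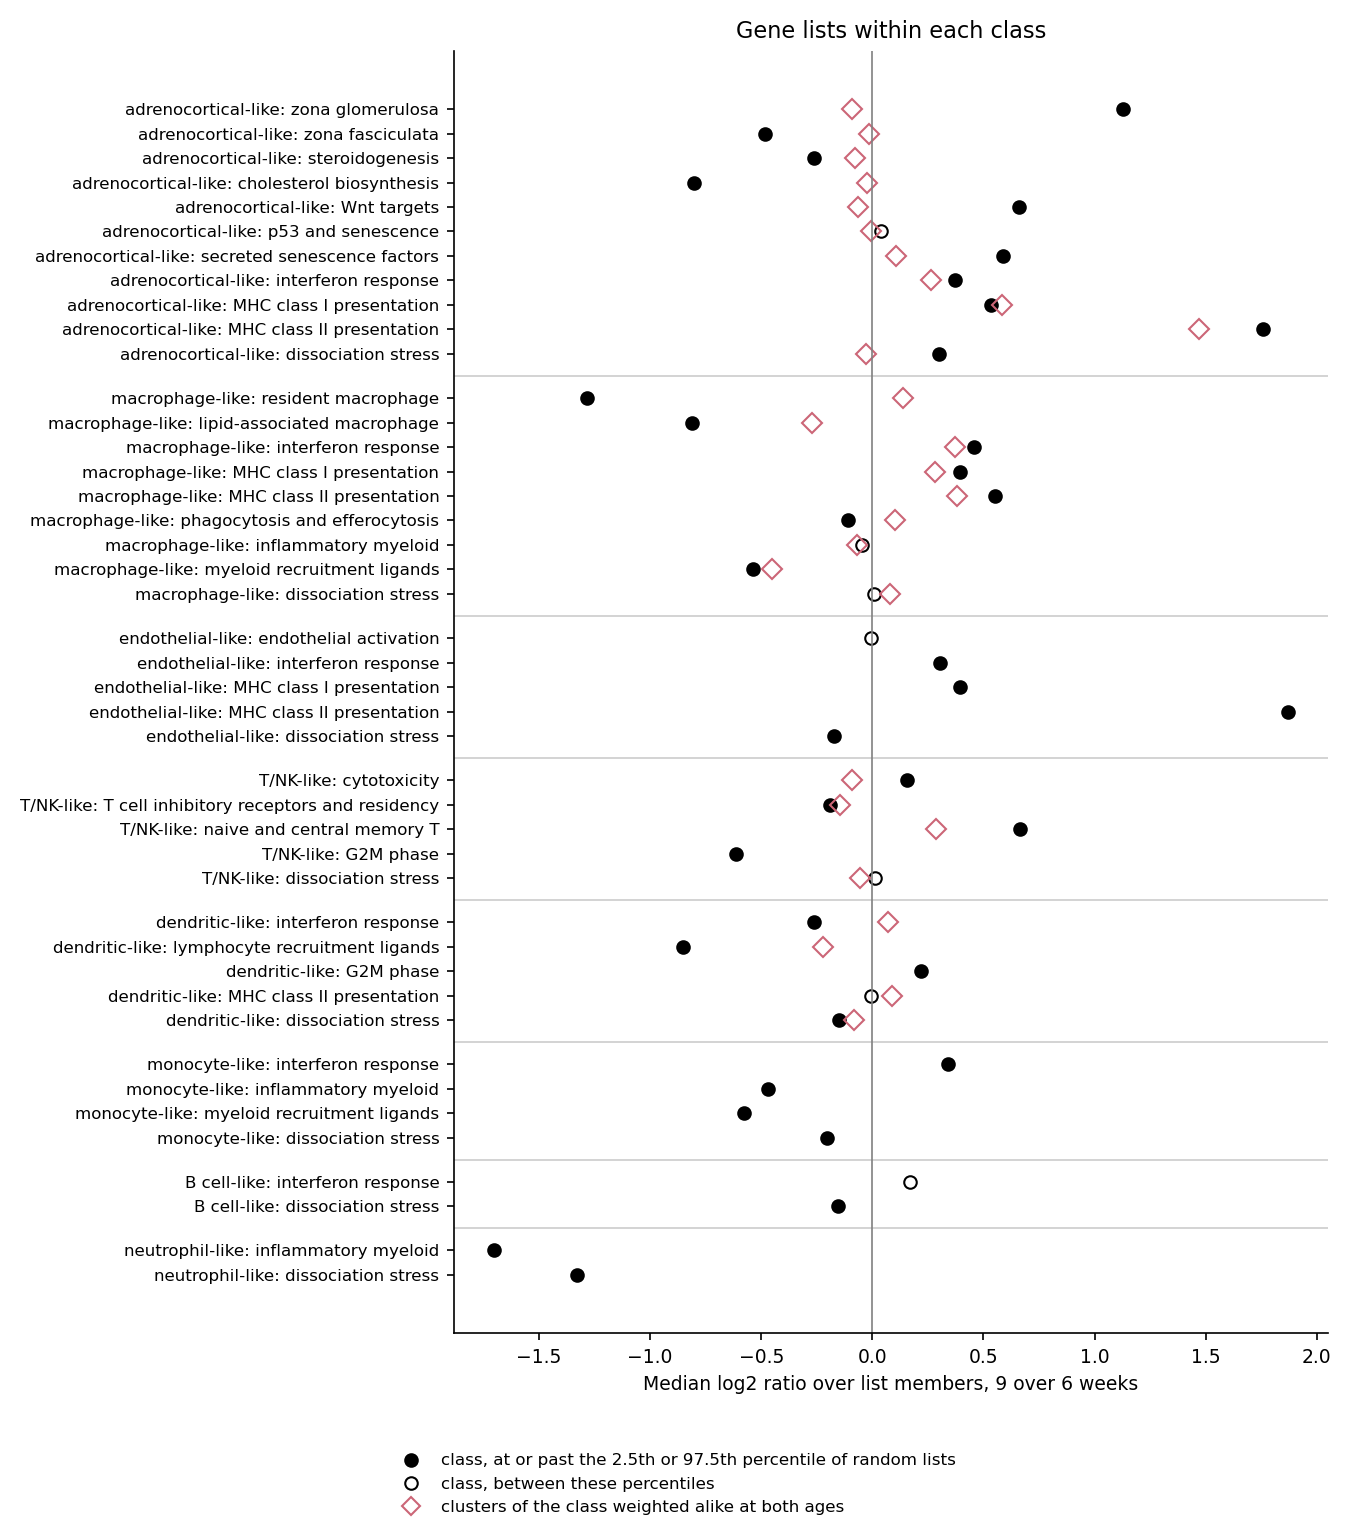
Median log2 ratio of 9 over 6 weeks for the gene lists described, by class, with filled circles for medians at or past the outer percentiles of random lists and open circles for others; diamonds give the value with the clusters of the class weighted alike at both ages, and none is drawn for G2 and M phase, since that setting leaves out the clusters led by cycle genes. The zona glomerulosa list moves from 1.13 to -0.090 and the resident macrophage list from -1.28 to 0.14, while MHC class I presentation in adrenocortical-like cells stays at 0.53 and 0.58.

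In macrophage-like cells, genes of tissue-resident and of lipid-associated macrophages were lower at 9 weeks, and interferon response and MHC genes were higher. Cluster 12, led by Pf4 and Mrc1 beside complement genes, held 327 of the 972 cells at 6 weeks and 46 of 2281 at 9 weeks, while cluster 1 held 426 and 1878. Of 16 resident macrophage genes, 10 were lower and 0 higher (median -1.28, percentile 0). Folr2 stood at 54.5 CPM (48.9 to 60.6) and 3.95 CPM (3.07 to 5.01), and Lyve1, a hyaluronan receptor, at 25.1 and 2.85 CPM. In cluster 1 alone this median was 0.0087, and with clusters weighted alike it was 0.14. Of 21 lipid-associated genes, 12 were lower and 0 higher (median -0.81, percentile 0, and -0.27 with clusters weighted alike). Trem2, a lipid receptor, stood at 593.9 CPM (575.0 to 613.2) and 277.9 CPM (270.0 to 285.8), Gpnmb at 68.3 and 32.9 CPM and Lpl at 305.7 and 127.4 CPM. These 3 genes are among the leading genes of cluster 22 (79 and 68 cells).

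Of 33 interferon response genes in macrophage-like cells, 9 were higher and 1 lower (median 0.46, percentile 100, and 0.37 with clusters weighted alike). Irf7 stood at 81.8 and 161.7 CPM. The gene that was lower, Cxcl9, which attracts T cells, stood at 154.3 and 60.0 CPM. Of 12 MHC class II genes, 6 were higher and 0 lower (median 0.55, percentile 100), such as H2-Eb1 (5627 and 9021 CPM) and Ciita, the master regulator of class II genes (114.7 and 201.3 CPM). The 15 MHC class I genes had a median of 0.40 (percentile 100) with 1 gene higher by 1.5-fold, H2-T23 (482.5 and 739.8 CPM). Chemokines that recruit myeloid cells were lower, with a median of -0.54 over 9 genes (percentile 0, 3 lower and 0 higher), and Ccl8 stood at 128.6 CPM (119.9 to 137.7) and 19.6 CPM (17.5 to 21.8). The inflammatory list had a median of -0.048 (percentile 7.77), with Il1b higher (43.9 and 78.8 CPM) and Ccl3 lower (48.0 and 25.6 CPM). The 26 phagocytosis and efferocytosis genes had a median of -0.11 (percentile 0.41), with 3 lower, such as the scavenger receptor Cd36 (271.7 and 154.8 CPM), and 1 higher, and a median of 0.0999 with clusters weighted alike. The dissociation stress list had a median of 0.0071 (percentile 34.3).

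Under the fixed rule, 4 genes were higher in macrophage-like cells at 9 weeks, namely Adamdec1 (17.3 and 70.8 CPM, log2 1.76), Gbp8 (1.32), Rgs1 (1.14) and Fcgr4 (284.3 and 575.2 CPM, log2 1.00), an activating Fc receptor. The 10 lowest ratios were those of Fcrls (210.1 and 20.7 CPM, log2 -3.07), F13a1 (-2.54), Pmp22 (-1.94), Cbr2 (-1.84), Ltc4s (-1.73), Fabp5 (-1.71), Cd163 (-1.42), Ninj1 (-1.32), Lpl (-1.23) and Lgals1 (-1.22). With clusters weighted alike F13a1 (0.13) and Cd163 (0.32) were higher at 9 weeks, while Adamdec1 (1.23), Gbp8 (1.07), Rgs1 (1.24), Fcrls (-1.14), Pmp22 (-1.38) and Lpl (-1.02) still had a log2 ratio of at least 1 in size.

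**Figure D3:**
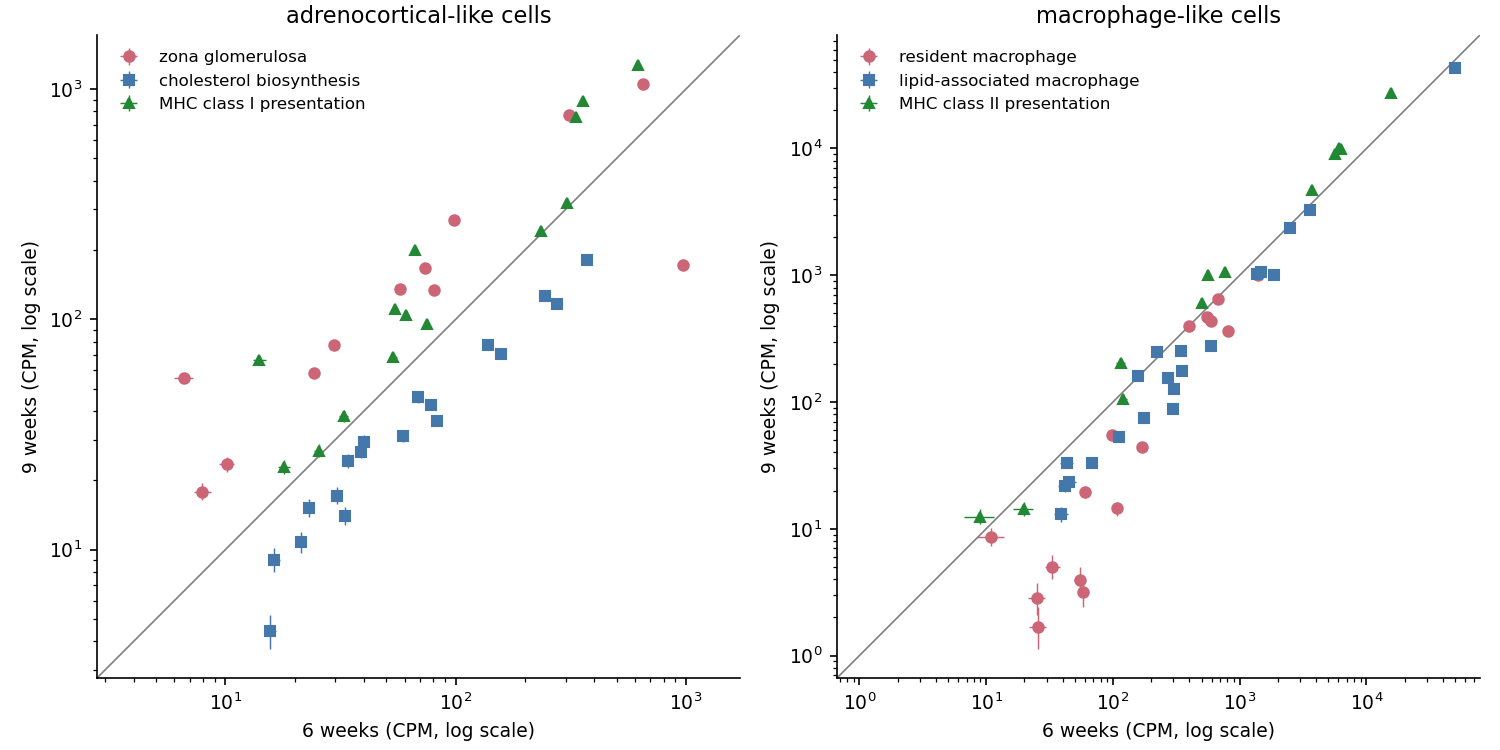
Level at 9 weeks against level at 6 weeks, in CPM on log scales, of the members of 3 lists in adrenocortical-like cells (left) and of 3 lists in macrophage-like cells (right); points are genes, lines exact 95% Poisson intervals and the diagonal equal levels. Cholesterol biosynthesis genes lie below the diagonal, with Fdps at 275.3 and 116.1 CPM, and none of the resident macrophage genes lies above it by 1.5-fold, with Folr2 at 54.5 and 3.95 CPM.

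Endothelial-like cells, which formed a single cluster, had higher interferon response and antigen presentation genes at 9 weeks, and a median of activation genes near 0. Of 33 interferon response genes, 7 were higher and 2 lower (median 0.30, percentile 100). Zbp1, a sensor of nucleic acids, stood at 66.1 and 130.9 CPM, while the chemokines Cxcl9 (42.5 and 14.5 CPM) and Cxcl10 (87.4 and 34.0 CPM) were lower. Of 15 MHC class I genes, 3 were higher and 0 lower (median 0.40, percentile 100), among them Tap1, of the peptide transporter (113.0 and 208.0 CPM). Of 10 MHC class II genes, 9 were higher (median 1.87, percentile 100), with Cd74 at 121.0 CPM (109.9 to 133.0) and 1007 CPM (977.5 to 1037) and H2-Aa at 72.5 and 341.8 CPM. The class II list was also higher in T/NK-like (0.77) and neutrophil-like cells (2.00), where Cd74 stood at 473.6 and 682.7 CPM at 9 weeks. Myeloid genes were higher as well in endothelial-like cells, with C1qa at 21.4 and 69.8 CPM and Ctss at 11.1 and 44.9 CPM, and with free RNA subtracted the interferon, class I and class II medians were 0.31, 0.40 and 1.71. As in adrenocortical-like cells, the subtraction cannot decide how much free RNA added to these lists. The 10 endothelial activation genes had a median of -0.0078 (percentile 42.6), with 2 lower, again Cxcl9 and Cxcl10, but a mean of -0.25 (percentile 0.78). The dissociation stress list had a median of -0.17 (percentile 0.13), with 0 of 12 genes past 1.5-fold. By the fixed rule, Plaat3 (12.2 and 97.9 CPM, log2 2.58), Tgtp1 (1.02), Kcne3 (1.02) and Tgtp2 (1.00) were higher, of which Tgtp1 and Tgtp2 are interferon-induced GTPases with near-identical sequences that can share reads. Fxyd6 (133 and 3.62 CPM, log2 -4.00), Pttg1 (-2.72), Chchd10 (-1.34), Hjurp (-1.16) and Ltbp4 (-1.05) were lower.

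Dendritic-like cells had fewer transcripts of chemokines that attract lymphocytes at 9 weeks, and about equal class II levels. The largest cluster, 7, led by Xcr1 and Clec9a of type 1 conventional dendritic cells, held 143 of 284 cells at 6 weeks and 728 of 1146 at 9 weeks, and cluster 25, with 4 and 75 cells, also had the T cell genes Trbc2, Nkg7 and Ms4a4b among its leading genes. Of 7 lymphocyte recruitment ligands, 4 were lower and 0 higher (median -0.85, percentile 0), with Cxcl9 at 293.4 CPM (275.8 to 311.7) and 69.8 CPM (65.9 to 73.8), Ccl5 at 379.9 and 126.2 CPM and Ccl22 at 41.2 and 20.6 CPM. These 3 genes and Ccl17 are among the leading genes of cluster 24, which held 30 and 55 cells, and S100a4 and Ccl9 among those of cluster 19, with 77 and 125 cells, so both clusters held a smaller part of the class at 9 weeks. In cluster 7 alone this median was -0.070, and it was -0.22 with clusters weighted alike. The 29 interferon response genes had a median of -0.26 (percentile 0, 5 lower and 0 higher), but 0.17 in cluster 7 alone and 0.068 with clusters weighted alike. The 14 class II genes had a median of -0.0062 (percentile 32.4, 0 past 1.5-fold). The 29 genes of G2 and M phase had a median of 0.22 (percentile 99.99, 1 higher), with Mki67, a marker of proliferation, at 96.1 and 150.9 CPM, but of 0.13 as a mean over cells (percentile 96.9). Without the clusters led by cycle genes it was 0.38 with clusters weighted alike and 0.10 in cluster 7 alone (percentile 69.4). The dissociation stress list had a median of -0.15 (percentile 0.12, 3 of 13 genes lower and 1 higher). By the fixed rule Ctla2b (log2 1.27) was higher, and S100a4 (-2.31), Cxcl9 (-1.997), Ccl9 (-1.82), Ccl17 (-1.70) and Serpina3g (-1.65) were lower, of which Ccl9 (0.23) and Ccl17 (0.34) were higher in cluster 7 alone. Ctla2b (1.07) and S100a4 (-1.24) kept a log2 ratio of at least 1 in size with clusters weighted alike, while Cxcl9 (-0.85), Ccl9 (-0.77), Ccl17 (-0.58) and Serpina3g (-0.88) were under it.

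Monocyte-like cells, a single cluster, had higher interferon response and lower inflammatory genes at 9 weeks. Of 33 interferon response genes, 4 were higher and 1 lower (median 0.34, percentile 100), with Isg15, a ubiquitin-like modifier, at 231.0 CPM (202.5 to 262.5) and 355.4 CPM (330.7 to 381.6). Of 11 inflammatory genes, 5 were lower and 0 higher (median -0.47, percentile 0), with Ccl4 at 124.3 CPM (103.6 to 147.9) and 29.8 CPM (22.96 to 38.1) and Tnf at 32.3 and 14.0 CPM. Of 8 ligands that recruit myeloid cells, 4 were lower and 0 higher (median -0.58, percentile 0), with Ccl8 at 140.0 CPM (118.0 to 164.9) and 6.52 CPM (3.57 to 10.9). The dissociation stress list had a median of -0.20 in this class (percentile 0.125), with 3 of 17 genes lower and 0 higher. T cell genes, which monocytes should lack, were higher as well, with medians of 1.03 for cytotoxicity (percentile 100), 0.56 for naive and central memory genes and 0.47 for inhibitory receptors. By the fixed rule Arsb (1.72), Ifit1 (1.16), Evi5 (1.11) and Ifit2 (1.06) were higher, and Fabp5 (-1.70), Ear2 (-1.24), Sdc4 (-1.22), Cyp51 (-1.11) and Dusp2 (-1.10) lower. The rule also named Chil3 as higher, which leads this cluster and is among the leading genes of the neutrophil-like cluster 13.

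T/NK-like cells had higher naive and central memory genes at 9 weeks and lower transcripts of mitotic genes. Their clusters 8, 15, 16 and 18 held 179, 65, 44 and 94 cells at 6 weeks and 480, 212, 231 and 135 at 9 weeks. Of 8 naive and central memory genes, 4 were higher and 0 lower (median 0.66, percentile 100, and 0.29 with clusters weighted alike), among them the chemokine receptor gene Ccr7 (39.7 and 71.3 CPM). The MHC class II list was higher as well in this class (0.77, percentile 100, 6 of 10 genes higher), and the naive list in monocyte-like cells (0.56). Of 29 genes of G2 and M phase, 17 were lower and 0 higher (median -0.61, percentile 0). This median is of summed UMIs, in which deep cells weigh more. Clusters 23 and 50 had medians of 11462 and 15953 UMIs per cell, against 3880 in cluster 8. The share of cycling cells was 8.29% and 4.81% thinned, with overlapping intervals, and 8.64% and 8.11% unthinned. Clusters 23 and 50, led by cycle genes, are left out when clusters are weighted alike (0.0081, percentile 34.9) and in cluster 8 alone (0.092, percentile 64.1), so these medians do not bear on dividing cells. Of 17 cytotoxicity genes, 6 were higher and 1 lower (median 0.16, percentile 97.6), with Prf1, which forms pores in target cells, at 158.7 CPM (140.2 to 178.8) and 414.6 CPM (397.0 to 432.8), Gzma at 2232 and 4148 CPM, and Gzmc at 133.2 and 52.6 CPM. Prf1 and Gzma are among the leading genes of cluster 16. The cytotoxicity median was -0.090 with clusters weighted alike, and 0.056 (percentile 66.2) as a mean over cells. The 13 inhibitory receptor and residency genes had a median of -0.19 (percentile 0.04), with 1 lower by 1.5-fold, Lag3 (21.3 and 9.76 CPM), and 0 higher, and of -0.071 (percentile 23.1) where cycle-led clusters were left whole. The dissociation stress list had a median of 0.010 (percentile 32.95). By the fixed rule Zeb2 (log2 1.52), Klrg1 (1.39), Gzmk (1.39), Klra4 (1.38) and Prf1 (1.36) were higher and Txndc5 (-1.12) and Cks2 (-1.07) lower. Gzmk (1.43) and Txndc5 (-1.36) kept a log2 ratio of at least 1 in size with clusters weighted alike, while Zeb2 (0.86), Klrg1 (0.92), Klra4 (0.23), Prf1 (0.55) and Cks2 (-0.46) were under it.

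Neutrophil-like cells had fewer inflammatory transcripts at 9 weeks, when cluster 13 held 283 of their cells. Of 10 inflammatory genes, 7 were lower and 0 higher (median -1.70, percentile 0), with Il1b, a leading gene of cluster 9, at 3347 CPM (3149 to 3554) and 962.6 CPM (930.0 to 996.1), Nlrp3 at 242 and 54.5 CPM and Ptgs2, a cyclooxygenase, at 84.8 and 5.28 CPM. In cluster 9 alone the median was -0.35 (percentile 3.89). Genes of dissociation stress were lower too, 13 of 15 by 1.5-fold and 0 higher (median -1.33, percentile 0), among them Junb (1351 and 392.5 CPM), and in cluster 9 alone that median was -0.24 (percentile 4.28). The median over all genes of this class was -0.37, and trimmed mean scaling put a log2 factor of 0.54 on its 9-week levels. The rule named Camp, Chil3, Ltf, Ngp and Orm1 as higher, the first 4 of which lead cluster 13. It named Lars2 (-2.60), Anxa6 (-2.47), Slc44a1 (-2.23), Prr5l (-2.17) and St8sia4 (-2.11) as lower. In B cell-like cells, whose median over all genes was 0.12, the 26 interferon response genes had a median of 0.17 (percentile 68.0, 8 higher and 2 lower), which ran from -0.12 to 0.57 over the other settings. There Serpina3g (1.37), Mphosph10 (1.34), Lef1 (1.33), Cdc123 (1.28) and Rinl (1.27) were higher and Jun (-1.17) was lower, a member of the dissociation stress list, which had a median of -0.15 (percentile 0.76, 3 of 12 genes lower and 0 higher) that ran from -0.41 to 0.094 over the other settings. Each of these 6 genes had 42 UMIs or fewer at 6 weeks, and all but Mphosph10 stood below their level in another class, at 0.22 (Rinl), 0.25 (Jun), 0.39 (Lef1), 0.51 (Cdc123) and 0.55 (Serpina3g) of it. Cytotoxicity genes, which B cells should lack, were higher as well in this class (8 of 9, median 1.64, percentile 100).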

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

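The tests of immune and macrophage cells per endothelial cell and those of free RNA in genes that differ in every class were chosen after the result was seen, and the others before.

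Clusters with both neutrophil and monocyte markers stayed unnamed and held 0.735% of cells at 9 weeks (73 of 9932), against 0 of 8119 at 6 weeks, which allows a share of up to 0.0454%. They stood out because they lie outside the classes compared and above that limit. Their leading genes included Camp, Ngp and Lcn2, which also lead the neutrophil-like cluster 13, and in clusters 56 and 57 the granulocyte precursor genes Elane and Prtn3. The interferon response list was higher at 9 weeks in macrophage-like cells (median log2 ratio 0.46) and lower in dendritic-like cells (-0.26). The difference between these classes was not tested, and in the largest dendritic cluster alone the median was 0.17.

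The share of immune cells was 2.21 times as high at 9 weeks. Filters do not account for it, since its ratio stayed at 2.07 or above (up to 2.40) under 5 other settings of the gene, mitochondrial and doublet filters. Loss of adrenocortical cells alone would leave immune cells per endothelial cell alike, but these had a ratio of 2.60 (2.31 to 2.94), from 1.44 to 3.76. Blood left in the tissue would not add macrophages, and macrophages per endothelial cell had a ratio of 2.26 (1.95 to 2.61). This ratio covers macrophages only, so it cannot decide whether blood added cells of the other immune classes. Age, blood for those other classes, a loss of endothelial cells as well, and differences between animals or between preparations stay open as untested, since each age is 1 library.

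MHC class II genes were higher at 9 weeks in endothelial-like and adrenocortical-like cells, and macrophage-like and dendritic-like cells, which make most of this RNA, were more numerous then. In adrenocortical-like cells the difference came to 0.685% of the level in those cells (median over H2-Aa, H2-Ab1, H2-Eb1 and Cd74), against 0.724% for other myeloid genes, as free RNA or doublets would give. In endothelial-like cells it came to 3.36% against 1.30%, which is 2.58 times as much, more than the bound of 2 times that free RNA would keep. The lowest class II gene (2.70%) lay above 8 of the 9 other genes (0.0605% to 1.80%) but under Fcer1g (7.25%), which endothelial-like cells already had at 547 CPM at 6 weeks, and Cd74 stood at 682.7 CPM in neutrophil-like cells. Subtracting a free RNA profile left the class II median at 1.71 in endothelial-like cells (1.87 without it), but also at 1.74 in adrenocortical-like cells (1.76 without it), where the other myeloid genes moved alike, so it does not decide between them. Free RNA or doublets and expression by endothelial cells thus cannot be told apart here, and age stays open as untested.

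Among genes that differed alike in every class where they were measured, neutrophil-like cells left aside, 7 were higher and 5 lower at 9 weeks. For the higher ones (Lcn2, S100a8, S100a9, Chil3, Camp, Ngp and Retnlg) the class with the second-highest level had a median of 0.00275 times the highest (0.00174 to 0.606), as RNA freed from neutrophils would give. The 0.606 is that of Chil3, with 2986 CPM in monocyte-like cells at 9 weeks, so this reading holds for the other genes only. For the lower ones (Ctse, Gm12166, Gm42418, AY036118 and Gm47283) it was 0.666 (0.637 to 0.972), which argues against RNA from 1 class, and Gm42418, which overlaps ribosomal RNA, stood at 5061 and 1415 CPM in macrophage-like cells. Gm47283, which the annotation places on chromosome Y (90784738 to 90816464), stood at 79.1 and 12.6 CPM in adrenocortical-like cells. Its level does not speak against the female sex in the labels, since 4 other genes of that chromosome held 2 UMIs in all at 6 weeks and 0 at 9 weeks. The 12 genes lie on 8 chromosomes, so 1 stretch of chromosome of another origin in the mice of 1 age cannot hold them all, and for part of them it cannot be told apart from chance: 50% had another within 5 Mb (percentile 99.9 of random sets), but with overlapping or neighbouring genes joined this was 20% (2 of 10 loci, those of Camp and Ngp, percentile 95.1). Camp and Ngp are among the genes read above as RNA freed from neutrophils, so these 2 loci do not speak for such a stretch. The 5 genes found when only classes that make a gene were judged were the 5 lower ones, and 0% of their 4 loci had another near (percentile 47.4). Random sets had a median of 0% too, so this percentile decides nothing. The 4 loci lie on 4 chromosomes, so 1 stretch cannot hold them all. A separate origin of single genes, age and preparation stay open as untested.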

How the results depend on the processing

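Of the alternatives, the largest cluster of a class alone, clusters weighted alike at both ages, cycle-led clusters left whole and mixed clusters kept were chosen after the data were seen, and the others before. The ratios of shares of all cells kept their direction, with 0.388 to 0.408 for adrenocortical-like cells, 2.07 to 2.40 for all immune cells, 1.79 to 2.02 for macrophage-like and 3.30 to 4.04 for dendritic-like cells over the alternatives planned. Of immune cells, the B cell share had a ratio on either side of 1 (0.851 to 1.27) and so had the T/NK share (0.925 to 1.063). Over all settings, 102 shares of cells stayed within their counting interval and 6 moved, as did 68 and 4 shares of immune cells, and all 45 ratios of cycling shares stayed, though within wide intervals: that of T/NK-like cells ran from 0.581 to 1.039 (with at least 1 UMI) and that of adrenocortical-like cells from 1.69 to 3.99 (doublets kept). Of list medians 822 kept direction and side of the percentiles, 32 were weaker, 11 passed a percentile they had not passed and 18 reversed. Of named genes 1136 kept direction and size, 134 fell under a log2 ratio of 1 and 7 reversed. For Znrf3, the mean over cells gave the same direction. Unless stated, the cause was not tested. No paired analysis was possible because the groups compared share fewer than 2 numbers, with 1 library each.

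With clusters weighted alike, the difference that lies between clusters is removed by construction. The medians then reversed for glomerulosa (-0.090), Wnt targets (-0.062), resident macrophages (0.14), phagocytosis (0.0999), T/NK cytotoxicity (-0.090), dendritic interferon (0.068) and cortical dissociation stress (-0.027), as did F13a1 (0.13) and Cd163 (0.32) in macrophage-like cells. Weaker were fasciculata (-0.016), cholesterol biosynthesis in adrenocortical-like (-0.022) and dendritic-like cells (-0.045) and secreted senescence factors (0.10). The largest cluster alone left out the other clusters and reversed fasciculata (0.11), cholesterol biosynthesis in adrenocortical-like (0.077) and dendritic-like cells (0.060), Wnt targets (-0.014), resident macrophages (0.0087), phagocytosis (0.087), dendritic interferon (0.17) and the genes Nr4a2 (-0.054), Rims2 (-0.28), Ccl9 (0.23), Ccl17 (0.34) and Cd163 (0.27). Weaker there were steroidogenesis (-0.097), cortical S phase (0.11), cortical dissociation stress (0.029), dendritic lymphocyte ligands (-0.070) and neutrophil inflammatory (-0.35) and dissociation stress genes (-0.24). For glomerulosa this setting gave no value, as too few members were measured in cluster 2. Clusters led by cycle genes fall outside both settings in immune cells, so their cell cycle medians do not bear on dividing cells. These were, for G2 and M phase, 0.0081 (weighted alike) and 0.092 (largest alone) in T/NK-like cells, and alone 0.10 in dendritic-like and 0.17 in macrophage-like cells, and for macrophage S phase -0.094 and -0.22.

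A minimum of 1000 genes per cell removes the shallow cells of small cell types. It gave ratios of 3.05 for the B cell share, 14.4 for neutrophils, 0.960 for endothelial-like and 2.40 for all immune cells, and of 1.27 and 5.98 for the B cell and neutrophil shares of immune cells. List medians under it were -0.12 for B cell interferon, on the other side of 0, 0.071 for secreted senescence factors and -0.089 for the macrophage inflammatory list. B cell interferon stood past a percentile with at least 200 genes (0.41), up to 10% mitochondrial UMIs (0.57), no such limit (0.45), doublets kept (0.35) and resolution 2 (0.46). B cell dissociation stress reversed with up to 10% mitochondrial UMIs (0.0098) and resolution 0.5 (0.094) and was weaker with doublets kept (-0.039) and as a mean over cells (-0.047). T/NK cytotoxicity was weaker with at least 200 genes (0.10), up to 10% mitochondrial UMIs (0.10), no such limit (0.12), doublets kept (0.12) and resolution 2 (0.14). It was also weaker with a pseudocount of 20 CPM (0.13) and with scaling without mitochondrial, ribosomal protein and haemoglobin genes (0.12). The same held with no filter on low genes (0.16, of which the percentile was 96.0) and with the mean over cells (0.056). Up to 10% mitochondrial UMIs also gave an immune ratio of 2.07, and doublets kept a secreted senescence median of 0.042 and a macrophage S phase median of 0.16. The mean over cells gave 0.13 for dendritic G2 and M phase, 0.20 for cortical dissociation stress and -0.56 for neutrophil inflammatory genes. The mean over members gave -0.15 for fasciculata, -0.15 for steroidogenesis, -0.25 for endothelial activation and -0.12 for phagocytosis. Each library clustered alone gave dendritic ratios of 4.04 and, of immune cells, 1.79. The marker score of each cell gave 0.912 for the monocyte share of immune cells. Cycle-led clusters left whole gave -0.071 for the T/NK inhibitory list.

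Depth limits the sparser classes most. Neutrophil-like cells held 318240 UMIs at 6 weeks and B cell-like cells 436433, so 10 CPM there stands for few molecules.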

Other observations

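The lists, gene sets and single genes of this part were picked out after their values were seen, and no explanation was tested.

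The cholesterol biosynthesis list had a median under 0 in monocyte-like, macrophage-like and dendritic-like cells as well as in adrenocortical-like cells, and above 0 in neutrophil-like cells. In adrenocortical-like cells this median was -0.022 with clusters weighted alike and 0.077 in cluster 2 alone. In monocyte-like cells 6 of 15 genes were lower by 1.5-fold and 0 higher (median log2 ratio -0.54, percentile 0), with Cyp51, lanosterol demethylase, at 77.3 and 33.1 CPM and Fdps at 117.5 and 54.0 CPM. In macrophage-like cells 10 genes had a median of -0.36 (percentile 0.01) with 0 past 1.5-fold, and of -0.45 with clusters weighted alike. In dendritic-like cells 13 genes had a median of -0.39 (percentile 0), 3 of them lower and 0 higher, and of -0.045 with clusters weighted alike and 0.060 in cluster 7 alone. In neutrophil-like cells 8 of 11 genes were higher and 1 lower (median 1.40, percentile 100), each with 17 UMIs or fewer at 6 weeks.

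Part of the cell cycle genes were higher at 9 weeks in macrophage-like and adrenocortical-like cells. In macrophage-like cells 5 of 26 genes of G2 and M phase were higher and 0 lower (median 0.47, percentile 100), with Top2a at 60.1 and 100.9 CPM and Mki67 at 44.0 and 82.6 CPM, while 0 of 14 S phase genes passed 1.5-fold (median 0.085, percentile 78.5). Without the clusters led by cycle genes, the G2 and M median was 0.33 with clusters weighted alike (percentile 99.5) and 0.17 in cluster 1 alone (percentile 85.5), and the S phase median was -0.094 (percentile 0.66) and -0.22 (percentile 0.01). In adrenocortical-like cells 5 of 11 S phase genes were higher and 0 lower (median 0.53, percentile 99.99), with Mcm6, of the replicative helicase, at 15.9 and 40.2 CPM, and a median of 0.15 with clusters weighted alike and 0.11 (percentile 81.1) in cluster 2 alone.

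Cells with transcripts of blood cell precursors were rare at 6 weeks. Cells that met the count for granulocyte precursor genes were 1 of 8119 (0.0123%, 0.000312 to 0.0686) at 6 weeks and 103 of 9932 (1.04%, 0.847 to 1.26) at 9 weeks. Those for B cell precursors were 9 (0.111%, 0.0507 to 0.210) and 29 (0.292%, 0.196 to 0.419), and those for erythroid precursors 1 and 12 (0.121%, 0.0624 to 0.211). These shares are of all cells, without thinning, and immune classes held 27.2% of all cells at 6 weeks and 60.3% at 9 weeks. The B cell-like share was itself 2.12 times as high at 9 weeks (1.63 to 2.78), so the counts do not show more precursors per B cell. At least 100 UMIs of late granule genes were held by 0 cells at 6 weeks and by 308 (3.101%, 2.77 to 3.46) at 9 weeks.

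Pttg1, which holds back sister chromatid separation, was lower at 9 weeks in adrenocortical-like (70.0 and 12.0 CPM) and endothelial-like cells (116.3 and 13.4 CPM), where dividing cells were few. In endothelial-like cells Fxyd6 was found in 21.6% of cells at 6 weeks and 1.00% at 9 weeks, and Plaat3 in 2.87% and 22.2%, at median depths of 2105 and 2619 UMIs.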
